A study of Mus musculus with 9 samples.

How the data were processed

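RNA was measured in microglia sorted magnetically from mouse brain at 2 weeks of age, in 9 libraries of 3 genotypes, with 3 libraries each. Per the labels, total RNA was taken up with QIAzol and libraries were made with a stranded TruSeq kit for messenger RNA. The deposited values are FPKM (fragments per kilobase of transcript and per 1e+06 mapped fragments), 1 column per library, for 24346 gene symbols. Per the labels, the authors used TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 on the mouse build mm10. The labels give neither the role of each tool nor the annotation, nor whether the FPKM were scaled between libraries. Read counts were not analysed here, so no counting interval was computed and tests made for counts were not used.

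Of the 24346 symbols, 6196 were listed at 0 in all 9 libraries. The FPKM were used as deposited, with no further scaling, and were set on the log2 scale after adding a pseudocount of 1. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, which left 12136 genes. A linear model with a term for the group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with expression. The 3 pairwise comparisons were two-sided, and p was adjusted by Benjamini-Hochberg over the 12136 genes within a comparison, with a threshold of 0.05 and no threshold on the fold change. Every adjusted p of a gene comes from this limma fit. Fold changes are those of FPKM plus the pseudocount, which draws them toward 1 for low values. Errors of group means are SD over n = 3 libraries, and errors of log2 changes are SE from the fit.

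Before the data were examined, 33 gene lists were fixed: microglial states, interferon and inflammatory genes, Mincle signalling, lysosomal and lipid metabolism, cell cycle, energy metabolism, stress, markers of 8 other cell types, neighbours of the targeted genes and sex-linked transcripts. Each of the 32 lists with at least 3 tested members was compared with all other tested genes by camera from limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The list of mitochondrially encoded genes had no measured member. Camera with a correlation estimated per list was run beside it, and no list passed with it in any comparison. Members were also counted after adjustment over the list alone. The fry test of limma, which asks only whether the members of a list move in one direction on balance, passed for 23, 5 and 22 lists in GD vs WT, GD_Mincle_KO vs GD and GD_Mincle_KO vs WT.

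The rule for named genes was also fixed before the data were examined. In each comparison it takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, leaving out predicted genes, then up to 4 members of smallest p from each list, and always Gba and Clec4e. Members outside this rule are given as chosen after their values were seen. Gba and Clec4e, the gene for Mincle, were also compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Changes of 2 comparisons were correlated across genes beside values from 100 simulated sets of unchanged groups with the same shared libraries. The position of GD_Mincle_KO between WT and GD was scored on genes chosen with 1 WT and 1 GD library held out, over all 9 such choices.

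The fit was tested on simulated data of 12136 genes with changes planted in known genes whose mean log2(FPKM + 1) was above 1. Noise was drawn independently for each gene and few genes were changed, so the rates need not hold for the real data. It recovered 64% of 50 genes planted at a log2 change of 0.5, 88% of 100 genes planted at 1 and 100% of 50 genes planted at 2. Of 178 calls, 8 were false (4.49%), and the comparison with nothing planted gave 0 calls. The pass mark of this test was first set on recovery at a log2 change of 1 and was moved to 2 after the 88% had been seen. Gene positions come from GENCODE on the same assembly. Symbols were matched to it for 95.6% of all symbols and 96.1% of the tested genes.

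Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, scaling to a common sum (TPM), quantile normalization, robust variances, fits on the 6 libraries compared, array quality weights, the replicate number as a factor, a principal component of the markers of other cells as covariate, a log2 change of at least 1, and each library left out in turn. A further alternative was added after seeing the data, without the libraries of extreme glial RNA (WT 3 and GD 2). Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.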

Results

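The experiment asks how microglia, the resident macrophages of the brain, differ in a mouse model of Gaucher disease and what the loss of a lipid-sensing receptor changes there. Messenger RNA was sequenced from microglia sorted from the brains of mice aged 2 weeks. Wild-type mice (WT) were compared with mice that carry loxP-flanked Gba and a Nestin-Cre transgene (GD) and with such mice that also lack Mincle (GD_Mincle_KO, the double mutant), with 3 libraries in each group. Gba encodes glucocerebrosidase, the lysosomal enzyme deficient in Gaucher disease, and Nestin-Cre acts in neural precursors and their progeny. Mincle, encoded by Clec4e, is a C-type lectin receptor of myeloid cells. The labels do not say that the libraries of a group come from separate animals, so every p measures the spread between these samples.

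The FPKM of a library summed to between 476236 (WT 2) and 559187 (GD_Mincle_KO 2), and between 15059 and 16328 symbols were above 0. Read totals were not analysed here. The steps between the lowest FPKM above 0 gave a depth relative to WT 1 of 0.926 and 0.979 in WT 2 and WT 3, 1.398, 1.286 and 1.045 in GD 1 to 3, and 1.022, 0.839 and 1.147 in GD_Mincle_KO 1 to 3. With the lengths of genes that have a single annotated transcript, this came to a rough 8.1 to 13.5 fragments per library in units of 1e+06. The first principal component held 65.5% of the variance and separated WT from both other groups, and the third, with 9.95%, separated GD from GD_Mincle_KO. Correlations across genes between libraries were 0.964 to 0.987 within WT, 0.977 to 0.990 within GD and 0.988 to 0.989 within GD_Mincle_KO, against 0.899 to 0.981 between groups.

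The targeted genes were read first. Clec4e (chromosome 6, 123281789 to 123289870, minus strand) was at 0.781, 0.932 and 1.85 FPKM in WT and 0.647, 0.192 and 0.590 FPKM in GD, and was listed at 0 in all 3 libraries of GD_Mincle_KO. It was too low for the fit, and the exact two-sided p of each pair of groups was 0.1, the smallest that 3 libraries against 3 allow. Gba (chromosome 3, 89202928 to 89208966, plus strand) was at 74.5, 71.4 and 75.1 FPKM in WT, 67.5, 52.8 and 51.7 FPKM in GD, and 44.9, 50.7 and 48.6 FPKM in GD_Mincle_KO. Its mean was 73.7 ± 2.01 FPKM in WT, 57.3 ± 8.84 FPKM in GD and 48.1 ± 2.94 FPKM in GD_Mincle_KO (SD, n = 3). Gba fell by 0.37 ± 0.096 on the log2 scale in GD against WT (limma adjusted p = 0.00897) and its log2 change was -0.61 ± 0.096 in GD_Mincle_KO against WT (limma adjusted p = 0.000428). Between GD_Mincle_KO and GD its log2 change was -0.24 ± 0.096 (adjusted p = 0.139). The Gba call in GD against WT was lost with the marker component as covariate, at a log2 change of -0.28, and without WT 3 and GD 2, at -0.30. Nestin-Cre need not act in microglia, and these values do not give the Gba level of neurons or other glia.

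**Figure D1:**
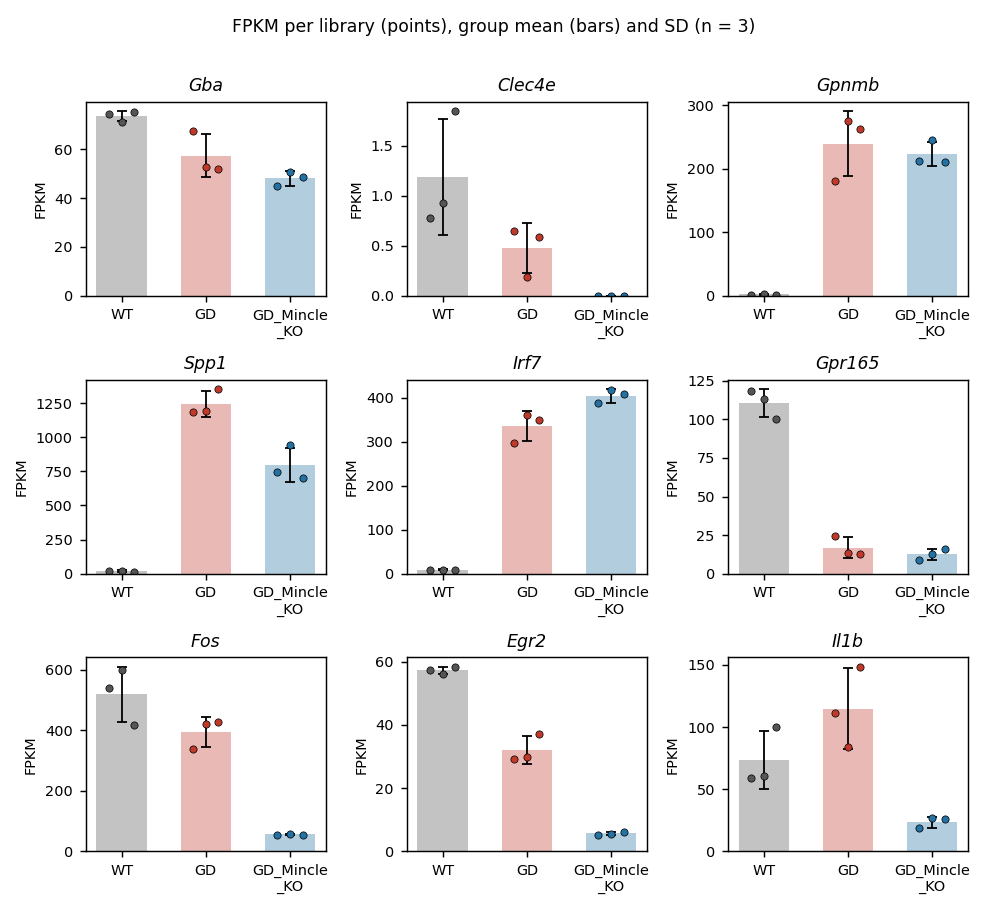
FPKM of 9 genes in each library (points), with the group mean (bars, axis from 0) and SD (n = 3) for WT, GD and GD_Mincle_KO. Clec4e was listed at 0 in the 3 GD_Mincle_KO libraries, Gpnmb, Spp1 and Irf7 were high in both mutant groups, and Fos, Egr2 and Il1b were lower in GD_Mincle_KO than in GD.

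The first comparison, GD against WT, asks what microglia look like when Gba is deleted in the neural lineage. Microglia of GD mice showed high levels of disease-associated, interferon and cell cycle genes and lower levels of the genes of resting microglia. Gpnmb, a lysosome-associated glycoprotein, was at 239 ± 51.3 FPKM in GD and 2.05 ± 1.25 FPKM in WT (82.1-fold), and Spp1, which encodes the secreted protein osteopontin, was at 1246 ± 95.4 FPKM in GD and 18.5 ± 4.12 FPKM in WT (64.7-fold; SD, n = 3). The chemokines Ccl5 and Cxcl10 rose 53.7-fold and 49.3-fold. Among the largest falls, Gpr165 went from 111 to 16.7 FPKM, Tlr5, the flagellin receptor, from 28.8 to 6.06 FPKM, and Mycl, a Myc family transcription factor, from 17.4 to 3.41 FPKM.

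All 36 tested members of the type I interferon list rose, with a median log2 change of 3.63 and a range of 0.76 to 5.62 (camera adjusted p = 6.37e-31, and adjusted p = 0.0665 with an estimated correlation). Irf7, a transcription factor that amplifies interferon production, was at 336 ± 34.5 FPKM in GD and 8.76 ± 0.505 FPKM in WT (log2 change 5.10 ± 0.078, SE). Isg15, a ubiquitin-like modifier, rose 26.2-fold, Zbp1, a sensor of nucleic acids, 23.3-fold, and the antiviral genes Rsad2 and Oasl1 41.2-fold and 40.2-fold. Oas1a rose 14.2-fold, although reads of the Oas1 genes are hard to assign. In the antigen presentation list, 13 of 23 members rose and 4 fell (median 0.85, camera adjusted p = 0.00027, and adjusted p = 0.174 with an estimated correlation). The risers included genes of the class I pathway, with Nlrc5, its transcriptional activator, at 11-fold and Tap1, a subunit of the peptide transporter, at 4.15-fold. The 4 that fell, chosen after their values were seen, were the class II genes H2-Aa, H2-Ab1 and H2-Eb1, at log2 changes of -0.60, -0.46 and -0.74, and the costimulatory gene Cd80, at -1.34. In the complement list, 11 of 18 members rose and 4 fell (camera adjusted p = 0.00533, and adjusted p = 0.19 with an estimated correlation), led by Cfb, a protease of the alternative pathway, at 201 ± 31.1 FPKM in GD and 4.55 ± 0.760 FPKM in WT. The complement call was lost under quantile normalization (adjusted p = 0.0733), where 8 rose and 5 fell. Counts adjusted over the list alone were the same for the interferon and complement lists, and 13 rose and 5 fell in the antigen presentation list.

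The lists of microglial state moved in opposite directions. Of 29 tested disease-associated genes, 28 rose and none fell, with a median log2 change of 2.07 (camera adjusted p = 3.55e-18, and adjusted p = 0.174 with an estimated correlation). The remaining member, Cd74, had a log2 change of -0.22 (adjusted p = 0.126). Cst7, an inhibitor of cathepsins, was at 270.1 ± 26.3 FPKM in GD and 8.36 ± 0.647 FPKM in WT. Axl, a receptor for the engulfment of dying cells, rose 16.3-fold and Lgals3, a galectin, 13.1-fold. Of 26 homeostatic genes, 25 fell and none rose, with a median of -0.89 (camera adjusted p = 2.27e-10, and adjusted p = 0.174 with an estimated correlation), and Hexb had a log2 change of -0.11 (adjusted p = 0.227). Slc2a5, a fructose transporter, fell by 1.92 ± 0.11 on the log2 scale, and Sall1, a transcription factor of microglial identity, went from 358 to 189 FPKM. Both lists gave the same counts adjusted over the list alone.

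Lysosomal genes rose for the most part: 27 of 40 hydrolases and membrane proteins were higher and 5 lower, Gba among the latter (median 0.50, camera adjusted p = 2.89e-07, and adjusted p = 0.311 with an estimated correlation). The protease Ctsz was at 2329 ± 176 FPKM in GD and 552 ± 30.2 FPKM in WT, Ctsb rose 3.50-fold, and Cd63, a protein of late endosomes, rose 3.60-fold. The other 4 that fell, chosen after their values were seen, were Npc1, Sgsh, Man2b1 and Pla2g15. The proton pump of the lysosome, the vacuolar ATPase, had 13 of 18 subunits higher and 1 lower, Atp6v0a1 (chosen after its value was seen; median 0.50, camera adjusted p = 3.1e-05, and adjusted p = 0.19 with an estimated correlation). Its subunit Atp6v1a rose 2.02-fold. In the lipid efflux and storage list, 11 of 24 members rose and 5 fell (median 0.33, camera adjusted p = 0.0309, and adjusted p = 0.333 with an estimated correlation). Lpl, a lipase, rose 11.4-fold, the fatty acid binding protein Fabp5 18.4-fold, and Plin2, a coat protein of lipid droplets, 3.39-fold. That lipid call was lost without GD 2 (adjusted p = 0.0671), with the marker component as covariate (0.0839), without WT 3 and GD 2 (0.068) and with a mean FPKM of at least 5 (0.108), and the lipid median was 0.21 under TPM scaling. The glycosphingolipid and ceramide list did not pass (7 of 31 rose and 9 fell, or 7 and 6 under median-of-ratios scaling, adjusted p = 0.807), and in it Gba2, the non-lysosomal glucosylceramidase, fell by 0.61 ± 0.076. Cholesterol biosynthesis did not pass either (4 rose and 1 fell of 24, or 3 and 5 under TPM scaling, adjusted p = 0.36), although Fdps rose 1.75-fold. Adjusted over the list alone, the counts were the same for the lysosomal, vacuolar ATPase and glycosphingolipid lists, with 12 risers for lipid efflux and storage and 3 for cholesterol biosynthesis.

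All 40 tested cell cycle genes were higher in GD, with a median log2 change of 2.29 (camera adjusted p = 3.55e-18, and adjusted p = 0.311 with an estimated correlation). Ccne1, a cyclin of the entry into DNA replication, was at 7.76 ± 1.03 FPKM in GD and 0.704 ± 0.381 FPKM in WT, and Cdk1, the kinase that drives mitosis, at 29.5 ± 2.84 FPKM in GD and 6.83 ± 1.95 FPKM in WT. Mcm5, part of the replicative helicase, rose 5.13-fold. Genes of energy metabolism rose as well. In the glycolysis and hypoxia list, 15 of 24 rose and 2 fell, Hk1 and Pfkfb4, chosen after their values were seen (median 1.0, camera adjusted p = 3.03e-07, and adjusted p = 0.174 with an estimated correlation). The glycolytic enzymes Pgk1, Tpi1 and Ldha rose 3.75-fold, 3.93-fold and 3.92-fold. Of 35 nuclear-encoded oxidative phosphorylation genes, 31 rose and none fell (median 0.62, camera adjusted p = 2.38e-11, and adjusted p = 0.174 with an estimated correlation), with Cox7b, a subunit of cytochrome c oxidase, at 2.06-fold. Of 40 ribosomal protein genes, 34 rose and none fell (median 0.41, camera adjusted p = 1.78e-08, and adjusted p = 0.546 with an estimated correlation). Their median was 0.26 under TPM scaling, with 27 higher and 1 lower, and 0.16 under quantile normalization, with 21 higher and 5 lower. In the oxidative burst and antioxidant list, 11 of 19 rose and 2 fell, Gclc and Cat, chosen after their values were seen (camera adjusted p = 0.000964, and adjusted p = 0.311 with an estimated correlation), and Cybb, the catalytic subunit of the phagocyte oxidase, rose 5.54-fold. In the unfolded protein and integrated stress list, 10 of 21 rose and 4 fell (camera adjusted p = 0.0213, and adjusted p = 0.174 with an estimated correlation). Psat1, an enzyme of serine synthesis, rose 4.75-fold. The median of that list was 0.10 and became -0.04 under TPM scaling, and its call was lost under quantile normalization (adjusted p = 0.0595) and with a mean FPKM of at least 5 (0.118). With p adjusted over the list alone, 32 oxidative phosphorylation genes rose, and the counts of the other lists of cell cycle, metabolism and stress were the same.

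Inflammatory genes were mixed: 19 of 28 rose and 3 fell, Ccl7, Nfkb1 and Tnfrsf1b, chosen after their values were seen (median 0.61, camera adjusted p = 4.51e-05, and adjusted p = 0.546 with an estimated correlation). Beyond Ccl5, the chemokines Cxcl9, Cxcl16 and Ccl12 rose 11.9-fold, 7.08-fold and 5.88-fold. Tnf, also chosen after its values were seen, was at 173 ± 52.8 FPKM in GD and 36.5 ± 12 FPKM in WT. The Mincle and C-type lectin list did not pass (3 rose and 10 fell of 17, adjusted p = 0.153, and 0.0481 as lower with every gene above 0 in 1 library kept). In it, Clec7a, the receptor Dectin-1, rose 9.99-fold and the signalling chain Fcer1g 1.58-fold, while Syk, the kinase downstream of both, fell by 0.90 ± 0.050. Phagocytic receptors went both ways (16 rose and 9 fell of 36, adjusted p = 0.153; median -0.03, mean 0.33), with the balance turned under TPM scaling (12 and 14) and quantile normalization (10 and 13), and Fcgr4, an activating antibody receptor, rose 7.50-fold. Autophagy genes did so too (6 rose and 7 fell of 22, adjusted p = 0.863; median -0.07, mean 0.01), with the receptor Optn at 3.32-fold. Of 24 immediate early and dissociation genes, 15 fell and 1 rose, Gadd45b, chosen after its values were seen (median -0.49, camera adjusted p = 0.00861, and adjusted p = 0.568 with an estimated correlation). Jun fell by 1.30 ± 0.085 and Egr2 went from 57.3 to 32 FPKM. That call was lost with the marker component as covariate (adjusted p = 0.0796) and without WT 3 and GD 2 (0.068). A difference in handling between GD and WT cannot be told apart from genotype for these genes. Adjusted over the list alone, the counts were the same for the inflammatory and Mincle lists, with 10 falls among phagocytic receptors, 8 among autophagy genes and 3 rises among immediate early genes.

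Markers of other cells also differed. Of 13 border macrophage markers, 9 fell and 1 rose (median -0.74, camera adjusted p = 0.0147, and adjusted p = 0.568 with an estimated correlation). Mrc1 fell by 1.15 ± 0.12 and F13a1 went from 122 to 56.2 FPKM, whereas Siglec1, which interferon also induces, rose 4.86-fold. The call of that list was lost with the marker component as covariate (adjusted p = 0.0778) and without WT 3 and GD 2 (0.068). Among 14 monocyte and neutrophil markers, 10 fell and 1 rose, Plac8 at 9.10-fold, and the list did not pass (adjusted p = 0.0989), although it did without GD 1 (0.0487), under median-of-ratios scaling (0.039) and with every gene above 0 in 1 library kept (0.0444). The neutrophil genes Retnlg, S100a9 and S100a8 went from 20.2 to 1.85 FPKM, from 72.5 to 11.4 FPKM and from 59.8 to 11.3 FPKM. Astrocyte markers did not pass (3 of 16 rose, median 0.75, adjusted p = 0.0878), although Gfap, a filament protein of astrocytes, was at 92 ± 37.1 FPKM in GD and 11.4 ± 11 FPKM in WT. The astrocyte list passed as higher without WT 1 (0.0379), WT 2 (0.0148), GD 1 (0.0403) or GD 3 (0.0367), under TPM scaling (0.0241), with the replicate block (0.0483) and with every gene above 0 in 1 library kept (0.0484). Nor did oligodendrocyte markers (2 of 11 rose, adjusted p = 0.111), with Cspg4 at 11 ± 2.76 FPKM in GD and 0.878 ± 0.738 FPKM in WT, although the list passed as higher without GD 1 (0.0291) or GD 3 (0.0401) and under TPM scaling (0.0401). In the remaining marker lists, Thy1 rose among 6 neuronal genes, Pecam1 fell among 15 endothelial genes, Cd4 and Cd79b fell among 5 lymphocyte genes, and no erythroid gene was called. Their adjusted p were 0.807, 0.902, 0.342 and 0.4, and the endothelial list passed as lower with the marker component as covariate (0.000447) and without WT 3 and GD 2 (0.000763). The neighbours of Clec4e (3 rose and 7 fell of 14) and of Gba (6 rose and 4 fell of 16) did not pass, with adjusted p of 0.414 and 0.4. Of 4 sex-linked transcripts, the Y-linked Ddx3y and Kdm5d fell by 0.61 ± 0.11 and fell by 0.47 (list adjusted p = 0.152). When adjusted over the list alone, 10 border macrophage markers fell, 2 astrocyte and 1 oligodendrocyte marker rose, 4 sex-linked transcripts fell, and the counts of the other lists of this group were the same. Cd4 lost its call without WT 3 or GD 3 (limma adjusted p = 0.056 to 0.0635).

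**Figure D2:**
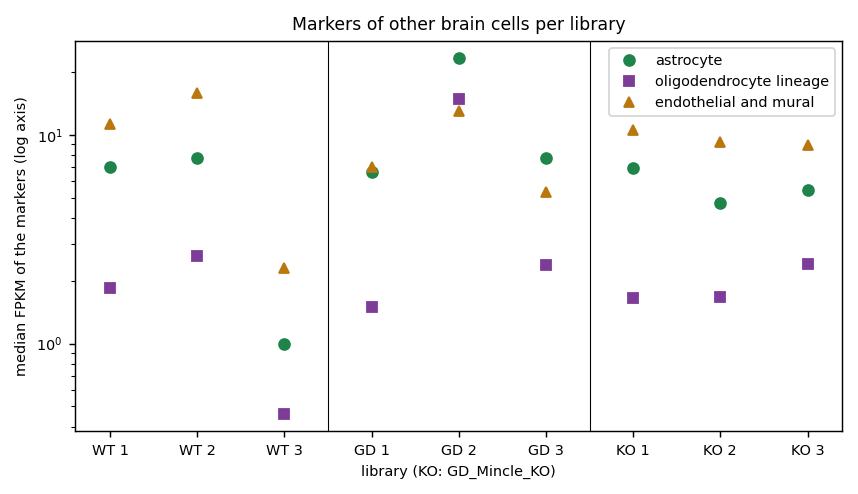
Median FPKM (log axis) of the astrocyte, oligodendrocyte lineage and endothelial markers in each library, with the groups separated by lines. GD 2 was highest for astrocyte and oligodendrocyte markers (23.2 and 14.9 FPKM) and WT 3 was lowest for all 3 lists.

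In total, 6723 of 12136 genes differed between GD and WT, 3003 higher and 3720 lower, and 1163 of them by at least 1 on the log2 scale, with 820 higher and 343 lower. The groups did not overlap for 7411 of all tested genes, against 10% by chance. The share of called genes that were higher was 44.7%, and it was 53.1% under median-of-ratios scaling (3300 higher and 2917 lower) and 32.1% under TPM scaling (2362 higher and 5000 lower), which shifts the median log2 change by -0.14. The balance of rises and falls therefore depends on the scaling, and the scaling of the deposited FPKM is not stated. The median changed sign between scalings for the phagocytic, glycosphingolipid, cholesterol, unfolded protein, autophagy and neuronal lists.

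**Figure D3:**
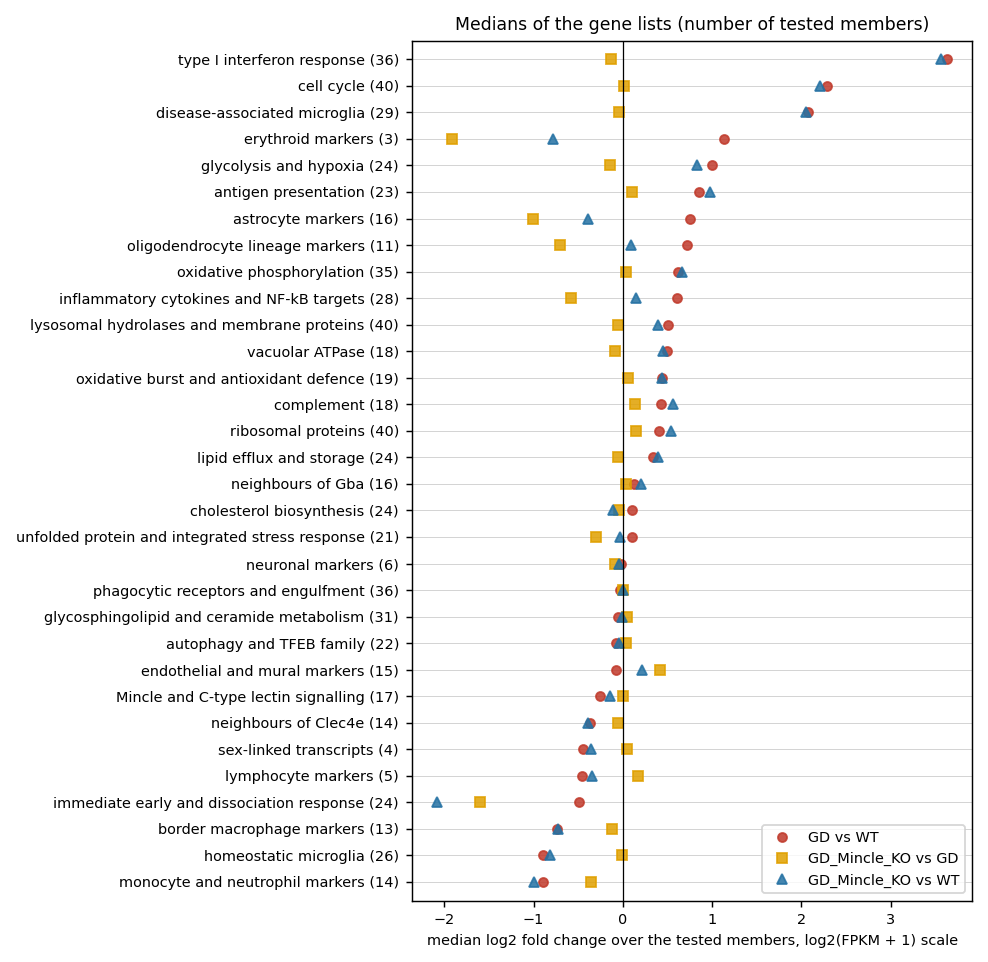
Median log2 fold change of the tested members of each gene list (number of members in parentheses) on the log2(FPKM + 1) scale, for GD vs WT (circles), GD_Mincle_KO vs GD (squares) and GD_Mincle_KO vs WT (triangles). The interferon median was 3.63 in GD vs WT and 3.57 in GD_Mincle_KO vs WT, and the immediate early median was -1.60 in GD_Mincle_KO vs GD. Medians of the phagocytic, glycosphingolipid, cholesterol, unfolded protein, autophagy, neuronal, Mincle, cell cycle, inflammatory and oligodendrocyte lists changed sign between scalings in at least 1 comparison.

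The second comparison, GD_Mincle_KO against GD, asks what the loss of Mincle changes in this model. Immediate early genes and 13 of 28 inflammatory genes were lower in the double mutant, while most of the genes that set GD apart from WT were not called. Fos went from 395 ± 50.3 to 55.9 ± 1.57 FPKM, Fosb from 52.5 ± 11.2 to 5.05 ± 0.814 FPKM, and Il1b, which encodes a cytokine of the inflammasome pathway, from 115 ± 32.5 to 23.5 ± 4.38 FPKM (SD, n = 3). Of 24 immediate early and dissociation genes, 21 fell, with a list median of -1.60 (camera adjusted p = 4.33e-25, and adjusted p = 0.135 with an estimated correlation). Egr2 fell by 2.31 ± 0.096 (limma adjusted p = 8.59e-06), Egr1 and Egr3 fell by 2.42 and fell by 2.08, and Zfp36, an RNA-binding protein that degrades cytokine transcripts, went from 1012 to 329.9 FPKM. Klf2 went from 87.2 to 15 FPKM and Nr4a1, a nuclear receptor, from 119 to 27 FPKM. Both members that rose, chosen after their values were seen, were the heat shock genes Hspa1a and Hspa1b, at log2 changes of 0.93 and 1.29, and Gadd45b was not called. Genes of this list also respond to the dissociation of tissue, and the labels give no handling day. The 21 falls were the same when adjusted over the list alone.

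**Figure D4:**
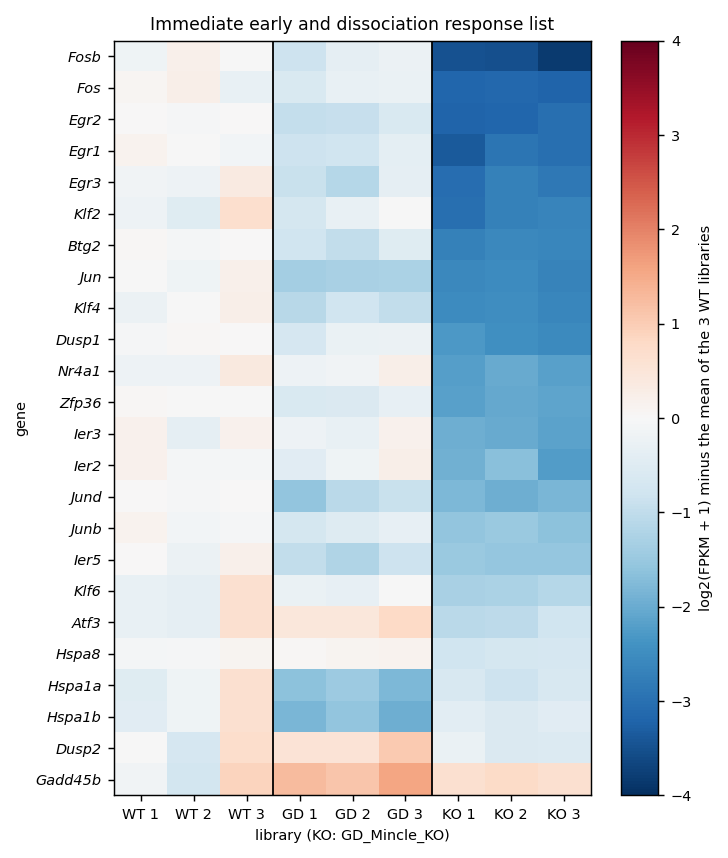
Log2(FPKM + 1) of the 24 members of the immediate early and dissociation list in each library, minus the mean of the 3 WT libraries (colour, blue lower and red higher). All 3 GD_Mincle_KO libraries (KO) were lower than GD for most members, with a median log2 change of -1.60, while Hspa1a and Hspa1b were lowest in GD.

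In the inflammatory list, 13 of 28 members fell and 1 rose (median -0.58, camera adjusted p = 7.12e-08, and adjusted p = 0.951 with an estimated correlation). The chemokine Ccl7 fell by 1.78 ± 0.13, Cxcl2 went from 25.9 to 3.87 FPKM, and Cxcl1 was at 3.74 ± 0.887 FPKM in GD and listed at 0 in GD_Mincle_KO. Nfkbid, a regulator of NF-kB that is not in this list, went from 81.8 to 16.8 FPKM. Tnf, chosen after its values were seen, went from 173 to 73.5 FPKM, against 36.5 FPKM in WT. Il1b, Cxcl2, Cxcl1 and Nfkbid instead fell below WT. Their WT libraries were at 59.2 to 100, 21.4 to 43.2, 2.34 to 4.17 and 105 to 149 FPKM. Il1b was at 18.5 to 26.4 FPKM in GD_Mincle_KO. A difference in handling between the groups cannot be told apart from genotype for these genes either. The member that rose, chosen after its values were seen, was Ccl5, at 477 ± 15.9 FPKM in GD_Mincle_KO and 229.6 ± 23.9 FPKM in GD. In the unfolded protein and integrated stress list, 9 of 21 fell and none rose (median -0.30, camera adjusted p = 1.27e-05, and adjusted p = 0.0573 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 592 ± 22.8 to 357 ± 10.1 FPKM, and Pdia4, Xbp1 and Hsp90b1 had log2 changes of -0.42, -0.37 and -0.37. With p adjusted over the list alone, 17 inflammatory genes fell and 2 rose, and 14 genes of the unfolded protein list fell. Hsp90b1 lost its call without GD_Mincle_KO 1 or GD_Mincle_KO 2 (limma adjusted p = 0.0505 to 0.0604), and Xbp1 without GD_Mincle_KO 2 (0.0576).

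The lists that defined GD against WT showed small changes. In the interferon list, 4 of 36 fell, of which Mx2 was chosen after its values were seen, and Ifitm3 rose (median -0.13, camera adjusted p = 0.0232, and adjusted p = 0.951 with an estimated correlation). Ifit1 fell by 0.67 ± 0.14. That call was lost without GD 3 (adjusted p = 0.125), without GD_Mincle_KO 1 (0.0605), with the marker component as covariate (0.0708) and with a mean FPKM of at least 5 (0.055). Of 29 disease-associated genes, 5 fell and Cd52 rose (adjusted p = 0.54, and 0.0356 as lower without GD 1). Clec7a went from 172 ± 17.6 to 94.3 ± 5.01 FPKM, and Spp1, chosen after its values were seen here, from 1246 to 798 FPKM. Clec7a, annotated as a polymorphic pseudogene, lies 6.18 Mb from Clec4e. Homeostatic genes had 2 rises, Sall1 and Cd33, and 2 falls, Fcrls and Rhob (adjusted p = 0.769). No cell cycle gene was called by limma (median 0.01, adjusted p = 0.922), while with the marker component as covariate the list passed as lower (adjusted p = 0.021). Lysosomal genes had 5 falls in 40, Ctsl and Pla2g15 among them (median -0.06, camera adjusted p = 0.0324, and adjusted p = 0.951 with an estimated correlation), and that call was lost without GD 2 (adjusted p = 0.122), GD 3 (0.125) or GD_Mincle_KO 1 (0.118), without WT 3 and GD 2 (0.0771) and with a mean FPKM of at least 5 (0.0759). In the vacuolar ATPase, 5 of 18 subunits fell and Atp6v0c rose (camera adjusted p = 0.0459, and adjusted p = 0.951 with an estimated correlation), with a median of -0.09. That call was lost without GD 2 (adjusted p = 0.0664), GD 3 (0.142), GD_Mincle_KO 1 (0.0687) or any library of WT (0.0565 to 0.0642), and also under median-of-ratios scaling (0.0565), with the compared groups alone (0.0886), without WT 3 and GD 2 (0.0766) and with a mean FPKM of at least 5 (0.144). Atp6v1e1, 2.48 Mb from Clec4e, fell by 0.53 ± 0.070. In glycolysis and hypoxia, 4 of 24 fell and Eno1 rose (median -0.15, camera adjusted p = 0.00986, and adjusted p = 0.951 with an estimated correlation), with Hif1a, the oxygen-regulated transcription factor, at a log2 change of -0.34. In cholesterol biosynthesis, Hmgcr, the rate-limiting enzyme, fell by 0.38 ± 0.081 as the single called gene of 24 (camera adjusted p = 0.0328, and adjusted p = 0.951 with an estimated correlation). The glycolysis and cholesterol calls were lost without GD 2 (adjusted p = 0.0932 and 0.443), and without WT 3 and GD 2 (0.0771 and 0.473). The cholesterol call was also lost without GD_Mincle_KO 2 (0.078), with array quality weights (0.112), with the marker component (0.104) and with a mean FPKM of at least 5 (0.144). Antigen presentation genes were slightly higher (median 0.11, camera adjusted p = 0.00845, and adjusted p = 0.563 with an estimated correlation), with B2m, the light chain of class I molecules, at a log2 change of 0.39 ± 0.075 and H2-Oa the other riser of 23. Ribosomal protein genes had a median of 0.15 (camera adjusted p = 0.00179, and adjusted p = 0.951 with an estimated correlation), lost without GD 2 (0.0559) and with the marker component as covariate (0.156), and 2 of 40, Rps11 and Rpl38, rose. Under quantile normalization the ribosomal median was 0.06, with 1 higher and 1 lower. Adjusted over the list alone, 13 interferon genes fell and 4 rose, 6 disease-associated genes fell and 4 rose, 3 homeostatic genes fell, 7 vacuolar ATPase subunits fell and 2 rose, 5 glycolysis genes fell, 3 antigen presentation genes rose, 0 ribosomal genes were called, and the counts of the cell cycle, lysosomal and cholesterol lists were the same. Atp6v0c lost its call without GD 1, GD 2, GD_Mincle_KO 1 or GD_Mincle_KO 2 (limma adjusted p = 0.0614 to 0.101), and B2m without GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0771 to 0.0775). Cd52 lost its call without GD 1, GD 2 or any library of GD_Mincle_KO (0.0587 to 0.0905), and Ctsl without GD 2, GD 3 or any library of GD_Mincle_KO (0.0526 to 0.0999). Eno1 lost its call without GD 1, GD 2, GD_Mincle_KO 1 or GD_Mincle_KO 3 (0.074 to 0.12), and Fcrls without GD 3 or any library of GD_Mincle_KO (0.0524 to 0.101). H2-Oa lost its call without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.0567 to 0.145), and Hmgcr without GD 2, GD 3 or any library of GD_Mincle_KO (0.0521 to 0.0905). Ifit1 lost its call without GD 1, GD 3, GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0597 to 0.084), and Ifitm3 without GD 1, GD 3 or any library of GD_Mincle_KO (0.0675 to 0.0994). Pla2g15 lost its call without GD_Mincle_KO 1, GD_Mincle_KO 2 or any library of GD (0.0575 to 0.102), and Rpl38 without WT 1, WT 2, GD 1, GD 2 or any library of GD_Mincle_KO (0.0562 to 0.168). Rps11 lost its call without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.0547 to 0.17), and Sall1 without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.0514 to 0.134).

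Among the largest single rises in GD_Mincle_KO, Eln, which encodes elastin, was at 91.1 ± 31.3 FPKM in GD_Mincle_KO and 16.3 ± 3.96 FPKM in GD, and Fbln5, a protein of elastic fibres, at 6.97 ± 2.45 FPKM in GD_Mincle_KO and 1.29 ± 0.138 FPKM in GD. Within each group, both ranked the libraries as the endothelial marker Vwf did, lowest in WT 3, GD 1 and GD_Mincle_KO 3. The median endothelial marker was also lowest in WT 3 and GD_Mincle_KO 3, but within GD in GD 3. RNA from endothelial or mural cells is therefore not excluded as the source of Eln and Fbln5. Plxnd1, a semaphorin receptor whose gene lies 7.31 Mb from Clec4e, rose 3.12-fold, Cirbp, a cold-inducible RNA-binding protein, 2.67-fold, and Cd209c, a C-type lectin, 2.94-fold. Cxcl13, a chemokine for B cells, was at 59.1 ± 23.4 FPKM in GD_Mincle_KO and 17.9 ± 3.23 FPKM in GD and listed at 0 in WT. Astrocyte markers were lower as a list (median -1.0, camera adjusted p = 0.00291, and adjusted p = 0.951 with an estimated correlation) with no single call by limma, and the call was lost without GD 2, the library of highest glial markers (adjusted p = 0.134). Erythroid markers had a median of -1.92 (camera adjusted p = 0.048, and adjusted p = 0.951 with an estimated correlation), again with no single call over all genes and 3 falls adjusted over the list alone, and that call was lost without WT 1 (adjusted p = 0.0565), GD 2 (0.135) or any library of GD_Mincle_KO (0.0502 to 0.0936), and under TPM scaling (0.091). Oligodendrocyte, neuronal, lymphocyte, border macrophage and sex-linked lists had no call, with adjusted p of 0.0814, 0.834, 0.609, 0.247 and 0.884. Of these, the oligodendrocyte list passed as lower without GD 1 (0.00399) or GD 3 (0.0125), under quantile normalization (0.0446), with the replicate block (0.0403) and with every gene above 0 in 1 library kept (0.0352), the border macrophage list as lower without GD 3 (0.00814), and the lymphocyte list as higher with every gene above 0 in 1 library kept (0.0352). The endothelial genes Vwf, 2.33 Mb from Clec4e, and Pecam1 rose and the neutrophil genes Cxcr2 and Retnlg fell, without a call of their lists (adjusted p = 0.545 and 0.565). The endothelial list had a median of 0.42 and passed as higher with the marker component as covariate (1.4e-05) and without WT 3 and GD 2 (0.00069). In lists that did not pass, called members were Clec7a and Syk (Mincle signalling, adjusted p = 0.834), St8sia1 and Gltp (glycosphingolipid, 0.746), Lpl and Plin2 (lipid storage, 0.915), C2 and C3 (complement, 0.162), Rac2 and Nfe2l2 (oxidative burst, 0.638), and Gabarap and Wipi1 (autophagy, 0.597). The list of phagocytic receptors and engulfment genes had 3 rises, C3, Rac2 and Fcgr4, and 2 falls, Msr1 and Itgb3 (0 and 2 under median-of-ratios scaling, adjusted p = 0.84). Oxidative phosphorylation had rises of Atp5g1 and Cox8a and a fall of Atp5a1 (1 and 2 under TPM scaling and quantile normalization, adjusted p = 0.642). Near Clec4e, Apobec1 rose 1.54-fold and A2m fell by 1.61 ± 0.34, and near Gba, Clk2 rose 1.23-fold (list adjusted p = 0.769 and 0.769). Of these, Fcgr4 was chosen after its values were seen. Among these lists, adjusted over the list alone, 3 complement, 4 phagocytic and 3 oxidative burst genes and 2 neighbours of Clec4e rose, Clk2 was not called, and the counts of the others except the erythroid list were the same. A2m lost its call without any library of GD or of GD_Mincle_KO (limma adjusted p = 0.0514 to 0.0834), and Atp5a1 without GD 2, GD 3 or any library of GD_Mincle_KO (0.0613 to 0.103). Atp5g1 lost its call without GD 1, GD 3 or GD_Mincle_KO 2 (0.0517 to 0.0642), and C2 without any library of GD or of GD_Mincle_KO (0.067 to 0.152). C3 lost its call without GD 1, GD 3 or any library of GD_Mincle_KO (0.0565 to 0.0957), and Clk2 without WT 1 or any library of GD or of GD_Mincle_KO (0.0644 to 0.147). Cox8a lost its call without WT 2 or any library of GD or of GD_Mincle_KO (0.0587 to 0.158), and Cxcl13 without GD_Mincle_KO 1 (0.0502). Cxcr2 lost its call without GD 1, GD 3, GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0528 to 0.0806), and Gabarap without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.0525 to 0.141). Gltp lost its call without GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.074 to 0.0802), and Itgb3 without GD 1 or any library of GD_Mincle_KO (0.0589 to 0.102). Lpl lost its call without GD 1, GD 3 or any library of GD_Mincle_KO (0.0514 to 0.101), and Nfe2l2 without GD 1, GD 3, GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0643 to 0.0905). Pecam1 lost its call without WT 1, GD 1, GD 3, GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0614 to 0.147), and Plin2 without GD_Mincle_KO 1 (0.0554). Rac2 lost its call without GD 1, GD 3 or any library of GD_Mincle_KO (0.0641 to 0.102), and Retnlg without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.052 to 0.109). Syk lost its call without WT 1, WT 2 or any library of GD or of GD_Mincle_KO (0.0507 to 0.129), and Vwf without WT 1, GD 1, GD 3 or any library of GD_Mincle_KO (0.0542 to 0.133). Wipi1 lost its call without GD 1, GD 3 or any library of GD_Mincle_KO (0.0601 to 0.132).

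In total, 1072 of 12136 genes differed between GD_Mincle_KO and GD, 574 higher and 498 lower, and 79 of them by at least 1 on the log2 scale, with 31 higher and 48 lower. At an unadjusted p of under 0.05 there were 3388 genes, and groups did not overlap for 4256 genes, against 10% by chance. The count was 520 without GD 1, 392 without GD 3, 234 without GD_Mincle_KO 1, 246 without GD_Mincle_KO 2 and 674 without GD_Mincle_KO 3. It was 646 under median-of-ratios scaling (291 higher and 355 lower), 1173 under TPM scaling (478 higher and 695 lower), 2186 with array quality weights, 1690 with the marker component as covariate and 1855 without WT 3 and GD 2. Of the 12 largest rises, Atp6v0c, Vaultrc5, Cxcl13, Vwf, Ly6h and Rpl37rt, and of the 12 falls Mir142b, were lost under at least 1 alternative. Vaultrc5 and Mir142b are short RNAs, for which FPKM are unreliable. Ly6h lost its call without GD 3 or GD_Mincle_KO 1 (limma adjusted p = 0.0543 to 0.0668), and Mir142b without GD 3, GD_Mincle_KO 2 or GD_Mincle_KO 3 (0.0625 to 0.0867). Rpl37rt lost its call without WT 1, GD_Mincle_KO 1, GD_Mincle_KO 2 or any library of GD (0.0586 to 0.152), and Vaultrc5 without GD 1, GD 2 or any library of GD_Mincle_KO (0.0708 to 0.0931).

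The third comparison, GD_Mincle_KO against WT, asks how far microglia of the double mutant stay from wild type. Interferon, disease-associated and cell cycle genes were high in them, and homeostatic and immediate early genes were low. Ccl5 was at 477 ± 15.9 FPKM in GD_Mincle_KO and 3.41 ± 1.31 FPKM in WT (112-fold), Gpnmb at 223 ± 19.1 FPKM in GD_Mincle_KO and 2.05 ± 1.25 FPKM in WT and Irf7 at 405 ± 15.8 FPKM in GD_Mincle_KO and 8.76 ± 0.505 FPKM in WT (SD, n = 3). Cxcl13 was at 59.1 ± 23.4 FPKM and listed at 0 in WT. Fosb, Fos, Egr2 and Egr1 went from 72.6 to 5.05 FPKM, from 519 to 55.9 FPKM, from 57.3 to 5.66 FPKM and from 397 to 45.6 FPKM.

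All 36 interferon genes rose (median 3.57, camera adjusted p = 3.27e-28, and adjusted p = 0.0838 with an estimated correlation), as did 28 of 29 disease-associated genes, all but Cd74 (median 2.05, camera adjusted p = 4.2e-17, and adjusted p = 0.222 with an estimated correlation), and all 40 cell cycle genes (median 2.21, camera adjusted p = 4.2e-17, and adjusted p = 0.365 with an estimated correlation). Isg15 rose 23.3-fold, Axl 16.8-fold, Tk1, an enzyme of thymidine salvage, 5.77-fold and E2f1, a transcription factor of S phase, 4.16-fold. Of 26 homeostatic genes, 24 fell (median -0.82, camera adjusted p = 3.17e-10, and adjusted p = 0.238 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell by 1.04 ± 0.062, and Rhob went from 1333 to 379.9 FPKM. Of 24 immediate early genes, 21 fell and none rose (median -2.08, camera adjusted p = 3.17e-10, and adjusted p = 0.255 with an estimated correlation), and Jun fell by 2.60 ± 0.085. Handling cannot be told apart from genotype for the immediate early genes in this comparison either. The inflammatory list did not pass, with 12 rises and 9 falls (10 and 11 under TPM scaling, 11 and 11 under quantile normalization) in 28 (adjusted p = 0.4). In it, Ccl5, Cxcl9, Cxcl16 and Ccl12 rose. Il1b and Cxcl2, chosen after their values were seen here, were lower in every GD_Mincle_KO library than in every WT library. Adjusted over the list alone, 25 homeostatic genes and 10 inflammatory genes fell, and the counts of the interferon, disease-associated, cell cycle and immediate early lists were the same.

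Lists of organelles and metabolism passed as well. Lysosomal genes had 27 rises and 6 falls in 40 (median 0.39, camera adjusted p = 1.2e-05, and adjusted p = 0.365 with an estimated correlation), with Npc2, a cholesterol-binding protein, at 2.01-fold. The lysosomal median was 0.21 under TPM scaling, with 21 higher and 9 lower, and 0.27 under quantile normalization, with 20 higher and 11 lower. The vacuolar ATPase had 13 rises and 2 falls in 18, the latter Atp6v0a1 and Atp6v1e1, chosen after their values were seen (camera adjusted p = 0.00102, and adjusted p = 0.364 with an estimated correlation). Antigen presentation had 14 rises and 4 falls in 23 (camera adjusted p = 6.08e-05, and adjusted p = 0.222 with an estimated correlation), and the falls, chosen after their values were seen, were again H2-Aa, H2-Ab1, H2-Eb1 and Cd80. Complement had 11 rises and 4 falls in 18 (camera adjusted p = 0.00465, and adjusted p = 0.25 with an estimated correlation), with C3 at 7.03-fold. Glycolysis had 16 rises and 2 falls, Hk1 and Hk3, chosen after their values were seen (camera adjusted p = 3.74e-05, and adjusted p = 0.292 with an estimated correlation), and Gapdh rose 3.91-fold. Oxidative phosphorylation had 30 rises and a fall of Ndufs1, chosen after its value was seen (camera adjusted p = 4.85e-10, and adjusted p = 0.238 with an estimated correlation), and ribosomal proteins 36 rises in 40 (camera adjusted p = 4.48e-10, and adjusted p = 0.442 with an estimated correlation). For the ribosomal proteins the median of 0.54 became 0.22 under quantile normalization, with 26 higher and 4 lower, and 0.36 under TPM scaling, with 34 higher and 3 lower. Medians also shrank under TPM scaling for the vacuolar ATPase (0.45 to 0.27), lipid (0.39 to 0.23) and oxidative burst lists (0.44 to 0.29), and under quantile normalization for complement (0.56 to 0.08). Oxidative burst genes had 11 rises and 4 falls (camera adjusted p = 0.0031, and adjusted p = 0.365 with an estimated correlation), with Sod1, a superoxide dismutase, at 2.03-fold. Lipid efflux and storage had 12 rises and 4 falls (camera adjusted p = 0.0316, and adjusted p = 0.365 with an estimated correlation), lost with a mean FPKM of at least 5 (adjusted p = 0.0517) and with the marker component (0.0534). Adjusted over the list alone, 28 lysosomal genes rose, 15 antigen presentation genes rose and 6 fell, 3 glycolysis genes fell, 37 ribosomal protein genes rose and 12 oxidative burst genes rose, and the other counts of these lists were the same.

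Border macrophage markers had 9 falls and a rise of Siglec1 in 13 (median -0.73, camera adjusted p = 0.00783, and adjusted p = 0.503 with an estimated correlation). Monocyte and neutrophil markers had 10 falls and 2 rises in 14 (median -0.99, camera adjusted p = 0.0478, and adjusted p = 0.507 with an estimated correlation), the rises being Plac8 and Ly6c2, the latter chosen after its values were seen. That call was lost without WT 2 (adjusted p = 0.0689), WT 3 (0.0514), GD 3 (0.0509), GD_Mincle_KO 2 (0.0511) or GD_Mincle_KO 3 (0.0543), and with array quality weights (0.0575), the marker component (0.0602), a pseudocount of 0.1 (0.066), quantile normalization (0.0547), TPM scaling (0.225) and a mean FPKM of at least 5 (0.278). Retnlg was at 0.866 ± 0.356 FPKM in GD_Mincle_KO and 20.2 ± 1.01 FPKM in WT. The lists of unfolded protein (9 rises and 9 falls), phagocytic (14 and 9), Mincle signalling (3 and 7), glycosphingolipid (7 and 10), cholesterol (3 and 5) and autophagy genes (7 and 8) did not pass, with adjusted p of 0.677, 0.301, 0.301, 0.993, 0.85 and 0.993. Under TPM scaling the rises and falls were 7 and 10 (unfolded protein), 12 and 14 (phagocytic), 4 and 13 (glycosphingolipid), 0 and 10 (cholesterol) and 4 and 13 (autophagy). Median-of-ratios scaling gave 9 and 8, 14 and 8, 9 and 6, 4 and 2, and 7 and 6 for the same lists, and quantile normalization 7 and 9, 10 and 11, 6 and 10, 3 and 6, and 6 and 9. Nor did the astrocyte, oligodendrocyte, endothelial, neuronal, lymphocyte and erythroid markers, with adjusted p of 0.993, 0.661, 0.85, 0.954, 0.661 and 0.723. With the marker component as covariate the astrocyte and erythroid lists passed as lower (0.00469 and 0.0456), the former also without WT 3 and GD 2 (0.00827). Called members of these were Gfap, Cspg4 and Slc2a1, which rose, and Pecam1, Cd4 and Cd79b, which fell. Near Clec4e, 2 of 14 genes rose, Apobec1 and C3ar1, and 8 fell (adjusted p = 0.298), near Gba 4 rose and 4 fell of 16 (6 and 2 under median-of-ratios scaling, 3 and 5 under TPM scaling, adjusted p = 0.392), and the Y-linked Ddx3y, Uty and Kdm5d fell (list adjusted p = 0.227). When adjusted over the list alone, 10 border macrophage markers fell, 1 cholesterol gene was called, Gfap and Slc2a1 were not called, and the other counts were the same. Gfap lost its call without WT 1, GD 1, GD 3 or any library of GD_Mincle_KO (limma adjusted p = 0.0542 to 0.101), and Kdm5d without WT 2 or GD_Mincle_KO 2 (0.0786 to 0.0839). Slc2a1 lost its call without GD_Mincle_KO 1 or GD_Mincle_KO 2 (0.0569 to 0.0599), and Uty without WT 1, WT 2 or any library of GD_Mincle_KO (0.0501 to 0.13).

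In total, 7069 of 12136 genes differed between GD_Mincle_KO and WT, 3204 higher and 3865 lower, and 1349 of them by at least 1 on the log2 scale, with 927 higher and 422 lower. Groups did not overlap for 7933 genes, against 10% by chance. Under TPM scaling 2384 were higher and 5267 lower (31.2% higher, against 45.3%), with the median log2 change shifted by -0.17, and under median-of-ratios scaling 3432 were higher and 3211 lower. The medians of the inflammatory, phagocytic, glycosphingolipid, unfolded protein, autophagy and oligodendrocyte lists changed sign between scalings. Of the 24 genes of largest change, Rnaset2a and Snora31, a short RNA, were lost under at least 1 alternative. Rnaset2a lost its call without WT 2, WT 3 or any library of GD_Mincle_KO (limma adjusted p = 0.064 to 0.085), and Snora31 without any library of GD or of WT (0.058 to 0.105).

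The double mutant lay close to GD on the axis from WT to GD. On genes that differed between the other WT and GD libraries, with 0 at WT and 1 at GD, held-out WT libraries scored 0.0670 ± 0.0931, held-out GD libraries 0.958 ± 0.0786 and GD_Mincle_KO libraries 0.947 ± 0.0128 (SD, n = 3), over choices of 1163 to 1422 genes. Across genes, which are not independent replicates, log2 changes of GD vs WT correlated with those of GD_Mincle_KO vs WT at r = 0.90 (rho = 0.84), against 0.50 simulated for unchanged groups that share WT libraries. With GD_Mincle_KO vs GD the correlation was -0.12 (rho = -0.13), against -0.50 simulated for the shared GD libraries, with covariances of -0.0271 observed and -0.0204 simulated. Of genes higher in GD than WT, 154 were lower and 118 higher in GD_Mincle_KO than in GD, where independence gives 123 and 142. Of genes lower in GD than WT, 284 were higher and 166 lower in GD_Mincle_KO, where independence gives 176 and 153. The shared GD libraries alone favour such opposite pairs, and they were not split here, so part of the excess may come from them.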

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

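All alternatives fixed before the data were examined were run, and the fit without WT 3 and GD 2, the libraries of extreme glial RNA, was chosen after seeing the data. Counts of changed genes stayed within 1.5 times the reported ones under the alternatives, with these exceptions. Requiring a log2 change of at least 1 left 1163 genes in GD vs WT, 79 in GD_Mincle_KO vs GD and 1349 in GD_Mincle_KO vs WT, because that setting is a stricter rule. The count of GD_Mincle_KO vs GD, 1072, was 646 under median-of-ratios scaling, 2186 with array quality weights, 1690 with the marker component as covariate and 1855 without WT 3 and GD 2, and the cause was not tested. Leaving out each library in turn gave 234 (without GD_Mincle_KO 1) to 1538 (without WT 3) genes, with 520 without GD 1, 392 without GD 3, 246 without GD_Mincle_KO 2 and 674 without GD_Mincle_KO 3. For the other comparisons the ranges were 5923 to 6625 (GD vs WT) and 6199 to 7200 (GD_Mincle_KO vs WT). The lists past the threshold, 17, 12 and 16 in GD vs WT, GD_Mincle_KO vs GD and GD_Mincle_KO vs WT, became 0, 0 and 0 with an estimated correlation, which gave the highest adjusted p of all settings run for each of them. In GD_Mincle_KO vs GD, 7 lists passed with a mean FPKM of at least 5, and 5 (without GD 2) to 14 (without GD 1) with each library left out. Apart from the estimated correlation, 12, 4 and 14 lists kept their call in every setting run, the 4 being antigen presentation, immediate early, inflammatory and unfolded protein genes. The Gba change in GD vs WT was -0.28 with the marker component and -0.30 without WT 3 and GD 2, no longer past the threshold, and -0.30 to -0.49 with each library left out. The position of GD_Mincle_KO, 0.947, was 0.919 with a pseudocount of 0.1 and 0.930 on genes changed by at least 0.5, and 0.848 (without GD 1) to 0.954 (without GD_Mincle_KO 1) with each library left out. The correlations of -0.12 and 0.90 were -0.14 to -0.11 and 0.88 to 0.90 with a pseudocount of 0.1, median-of-ratios scaling and quantile normalization. Directions reversed with the marker component for the cell cycle list in GD_Mincle_KO vs GD (adjusted p = 0.021, lower), for Plp1 (-1.12), Hba-a1 (-0.52) and Hbb-b1 (-0.77) in GD vs WT, and without WT 3 and GD 2 for Plp1 (-0.89), none of which otherwise passed the threshold, and the cause was not tested. For the lists, 1142 of 1239 values under other settings kept direction and side of the threshold, 78 were weaker, 18 stronger and 1 reversed, and with each library left out 826 of 864 did, with 27 weaker and 11 stronger. For the named genes the figures were 4722 of 4987 with 124 weaker, 137 stronger and 4 reversed, and 3466 of 3780 with 276 weaker and 38 stronger. With the replicate number as a factor the counts were 6713, 902 and 7099. After group means were removed, 5 of 9 libraries correlated best with a library of their own number. All pairs of equal number in GD vs WT ranged from -0.13 to 0.47. The numbers were not treated as pairs because the labels do not say that equal numbers belong together. Depth limits genes of low FPKM, Clec4e among them, and no interval was computed from FPKM.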

Other observations

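The tests in this part were chosen after the result was seen, except the test of genes near Clec4e called in both comparisons of the double mutant and the counts of other splits, which were set beforehand.

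Some genes outside the lists, chosen after their values were seen, were higher in both mutant groups than in WT. Irg1, the enzyme that makes itaconate in activated macrophages, was at 0.230 ± 0.246 FPKM in WT, 24.5 ± 3.84 FPKM in GD and 34.8 ± 0.783 FPKM in GD_Mincle_KO (SD, n = 3), a log2 change of 4.39 in GD vs WT. Serpina3n, a protease inhibitor of acute inflammation, was at 0.550 ± 0.546 FPKM in WT and 18 ± 5.80 FPKM in GD, and at 3.92 ± 0.574 FPKM in GD_Mincle_KO, where it was lower than in GD (log2 change -1.91, limma adjusted p = 0.00704). It was listed at 0 in WT 3, the library lowest in astrocyte markers. GD 2 and GD 3 were close, at 22.0 and 20.8 FPKM, although their median astrocyte markers were 23.2 and 7.75 FPKM. The cells that supplied Serpina3n RNA were not tested. Nes, the gene of the intermediate filament nestin, was at 7.20 FPKM in WT, 37.4 FPKM in GD and 30.2 FPKM in GD_Mincle_KO.

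Of the 24 immediate early and dissociation genes, 21 were lower in GD_Mincle_KO than in GD, with a median log2 change of -1.82. The tables argue against the return of a rise that GD had over WT, since these 21 had a median of -0.47 in GD vs WT with 0 called higher and 13 lower. RNA from other cell types was tested only as far as the marker component captures it. With this component as covariate the median was -1.80 and 21 of 21 stayed lower. These 21 were chosen as called lower in this comparison, and the covariate raised its calls from 1072 to 1690. That they stayed lower therefore decides little. The marker component is 1 component over all marker lists and cannot remove every difference in other cells. With it the endothelial list passed as higher (camera adjusted p = 1.4e-05), so RNA that it misses is not excluded. A difference in handling between the groups cannot be told apart from genotype, because the labels give no handling day, and the heat shock genes Hspa1a and Hspa1b went the other way, with a mean log2 change of 1.11. An effect of Mincle loss may account for the pattern and stays untested, because genotype cannot be separated from handling here. No group lacks Mincle on a WT background, so whether such an effect would need the deletion of Gba is not known either.

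All 40 cell cycle genes tested were higher in GD than in WT, with a median log2 change of 2.29, and the lowest median over 4 scalings was 2.27, which argues against scaling. Of 11 markers of blood cell progenitors, 4 were higher in mean FPKM in GD (median change -0.14 on the log2 scale) and 10 were under 1 FPKM in GD, the other being Cd34, at 125 FPKM in GD and 55.1 FPKM in WT. Cd34 was called higher (log2 change 1.16, limma adjusted p = 6.38e-07), as the single call among the blood cell markers. Of 12 markers of neural progenitors, 12 were higher (median change 0.19) and 8 were under 1 FPKM in GD, and Nes, at 7.20 FPKM in WT and 37.4 FPKM in GD, was the single call. Adding 1 to FPKM this low holds the medians near 0, and the bounds of both tests were changed after the values were seen, so neither source is excluded and both cannot be told apart from division of the microglia, which may account for the rise, as a hypothesis. Dividing oligodendrocyte precursors stay open as well: Cspg4 was at 8.07 to 13.5 FPKM in GD and 0.136 to 1.61 FPKM in WT, although the median oligodendrocyte marker of GD 1 and GD 3 (up to 2.37 FPKM) lay within the range of WT (0.462 to 2.61 FPKM) and the cell cycle call held with the marker component and without WT 3 and GD 2 (adjusted p from 2.35e-27 to 8.9e-16 over all settings but the estimated correlation, at 0.311).

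Genes called between GD_Mincle_KO and GD lay close to Clec4e more often than elsewhere: 22 of 150 tested genes within 10 Mb were called (14.7%, against 8.69% of all placed genes), among them Clec7a, Atp6v1e1, A2m and Vwf. Windows of as many neighbouring genes held a median of 13 calls and a 95th percentile of 20, and 4.11% of 876 windows held as many. Of the 150 genes, 15 were called in the same direction against GD and against WT (10%, against 4.88%), where windows had a median of 7 and a 95th percentile of 12 and 0.571% held as many, and Plxnd1, BC064078, Mical3 and Apobec1 had the smallest p of these. For both counts the windows overlapped one another and included the region of Clec4e itself. The shares of windows are therefore not shares of separate regions. DNA of the donor strain that flanks the targeted allele is a candidate explanation for some calls in this region, which held 22 of the 1014 placed calls. The strains are not in the labels, and an effect of Mincle on its neighbours stays open.

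The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. In GD vs WT the real split called 6723 genes and the highest other 87, in GD_Mincle_KO vs GD 1072 and 3, and in GD_Mincle_KO vs WT 7069 and 1. In each, 1 of the 10 splits, the real one, gave as many. Every other split mixes both groups, so any difference between them widens its spread and lowers its count. The counts of the other splits are therefore not levels expected without a difference.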
